A study of Mus musculus with 4 samples.

How the data were processed

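RNA-seq values of 4 libraries of plated rib chondrocytes from 10-day-old mice were used, 2 wild type and 2 Kdm6a/b knockout, with groups and replicate numbers taken from the sample titles. Per the submitters' processing notes, Bowtie2 2.2.5 and the mouse genome build mm9 were used. The tool that estimated the counts, the gene annotation release and the use of strand are not given in the sources used here. The authors deposited, per the file headers, an expected count and an FPKM value for each gene in each library, with an NCBI gene number, RefSeq transcripts and annotation terms. Expected counts are estimates that need not be whole, and 74.2% to 74.6% of them were whole within 0.005. The smallest FPKM listed in any library was 0.01, and a gene not listed for a library was taken as 0 there. The authors also deposited a comparison of control and knockout by DESeq2, with the mean signal of each group on the scale of normalized counts, a log2 fold change, a p-value and an adjusted p-value for each gene, per the file headers and file name.

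The 4 libraries listed 17575 genes in all, of which 15243 were in every library. 17518 of them matched the RefSeq gene table of the mouse assembly GRCm38.p6, which was used only for current names and chromosomes, since the files use mm9. For that reason no coordinates are given. 26 entries, holding 0.0271% of counts, were named by a transcript with no gene number and belonged to 20 genes. They were kept as separate entries and left out of the annotation terms and of the genes to be named, and were summed with their genes as an alternative. Identical or near-identical gene copies share reads in ways the deposited counts do not show.

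Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filter filterByExpr and quasi-likelihood F tests of knockout against wild type over all 4 libraries. P-values were adjusted by the Benjamini-Hochberg method over the 13773 tested genes, and a gene was called changed at an adjusted p under 0.05. Log2 fold changes are knockout minus wild type, standard errors are the log2 fold change over the square root of the F statistic, and expression is in TMM-scaled counts per library size (CPM) with the standard deviation over 2 libraries. The common dispersion gave a biological coefficient of variation of 10.3%. Depth was 31178248 to 32332044 counts per library, and 13556 to 13702 genes had at least 10 counts in a library. In every called gene both knockout libraries lay on the same side of both wild type libraries. Of all tested genes 8494 were separated in this way, where chance gives 33.3% with 2 against 2. Replicates differed by more than counting noise, with a chi-square per gene of 19.0 in wild type and 20.8 in knockout against 59.9 to 90.1 between groups, and each was counted as a replicate.

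38 gene lists were fixed, for programmes of cartilage, chromatin, cell cycle, signalling and stress, and for markers of other cell types. These lists, the tests, the rule for the genes to be named and most alternatives were chosen before the data were examined. The 36 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over those lists. No call of a list held with the correlation estimated from the data, which left 0 lists past 0.05. On simulated data of 13773 genes, a list built of changed genes had an unadjusted camera p of 6.2e-38 with the preset and 0.00941 with the estimated correlation. Of 100 random lists, 2 had a p under 0.05 with the preset and 0 with the estimated correlation. Genes were drawn independently there, so the simulation cannot say which setting is right for lists of genes that vary together. A list built only of changed genes came no lower than an unadjusted camera p of 0.00941 with the estimate, before any adjustment over 36 lists. Not passing with the estimated correlation therefore says little against a list. The fry test was an alternative, which tests whether a list moves in 1 direction without comparing it with other genes. Annotation terms with 10 to 500 tested members were tested with 1-sided Fisher's exact tests against all tested genes with terms, and adjusted over 2508 terms.

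Named genes were Kdm6a and Kdm6b, the 12 largest rises and 12 largest falls by log2 fold change among changed genes with an average of at least 5 CPM and separated groups, without predicted or clone names, and for each list up to 4 members with the smallest p-values, with the sex-linked genes Xist, Ddx3y and Uty. 446 rising and 665 falling genes were eligible. Genes outside the rule that are named, such as Col2a1, Acan, Sox9, Col10a1, Mki67, Chad, Col11a1, Hoxb9, Phlda2, Ibsp, Phex, Sp7, Lif, Ptges, Csf1r, Adgre1, Mrc1, Cd68 and the members of annotation terms, were chosen after their values were seen.

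The edgeR step was tested on simulated counts of the comparison of knockout with wild type, with 200 changed genes among 13773. It recovered 49.3% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold, and 10 of its 166 calls were false. Each simulated gene had the spread typical of its expression level, and changed genes were drawn from those averaging at least 1 CPM. In the real data spread also differs between genes of a level, so recovery may be lower and false calls more frequent there. Alternatives covered other scalings, filters and thresholds, DESeq2 1.42.0, limma on voom weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with FPKM of at least 1 in 2 libraries or no filter, the replicate number as a block, removal of X and Y genes, and each library left out in turn. With a library left out, the lone library of its group is assumed to vary like the other group. Added after seeing the data were the summed entries, DESeq2 with each library left out, and a correction of each library's log2 deviation by a loess surface with a span of 0.3 over transcript GC content and length, from GENCODE M21 transcripts that gave a value for 99.2% of genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.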

Results

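Chondrocytes, the cells that make cartilage matrix, were taken from the rib cartilage of 10-day-old C57/Bl6 mice by collagenase digestion and plated before RNA extraction, and gene expression was measured by RNA-seq. 2 libraries came from wild type mice and 2 from mice carrying a Col2-driven Cre recombinase, which acts in cartilage, with loxP-flanked alleles of both Kdm6a and Kdm6b, called the knockout here. Both genes encode demethylases that remove the repressive methyl mark from lysine residues of histone H3. The series description speaks of triplicates, and 2 libraries per group were analysed here. Estimated counts summed to 31616619 and 31178248 in the wild type libraries and to 32332044 and 32230980 in the knockout libraries, with 16199 to 16514 genes listed per library. Fn1, which encodes fibronectin, took the largest share of counts, from 4.39% to 6.09%. Col2a1, the main collagen gene of cartilage, took 2.60% and 2.37% of counts in the wild type libraries and 3.76% and 3.70% in the knockout libraries. Log2 expression correlated across genes with Pearson's r of 0.990 between the wild type replicates, 0.990 between the knockout replicates and 0.979 to 0.982 between libraries of different groups, although genes are not independent replicates. The first principal component held 58.9% of the variance and separated the groups. Nothing in the labels says whether the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

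The first question was whether the targeted transcripts were lower in the libraries labelled knockout. Kdm6b (gene 216850) measured 125 ± 9.2 CPM (counts scaled to a common library size, mean ± SD, n = 2) in wild type and 48.8 ± 3.7 CPM (n = 2) in knockout chondrocytes. Its log2 fold change, knockout minus wild type, was -1.35 (SE 0.091, edgeR adjusted p = 0.00174), a 2.56-fold fall. Kdm6a (gene 22289) fell from 54.8 ± 3.0 to 30.0 ± 2.0 CPM (n = 2 each), a log2 fold change of -0.87 (SE 0.087, edgeR adjusted p = 0.00489) and a 1.82-fold fall. Both genes were lower in 2 of 2 knockout libraries than in either wild type library. Counts per gene cover all exons and not the deleted part alone, so residual counts do not measure intact transcript. Without wild type replicate 1 the edgeR adjusted p-values were 0.101 for Kdm6a and 0.0936 for Kdm6b, and without wild type replicate 2 they were 0.181 and 0.158, with log2 fold changes of -0.92 and -1.28, and of -0.81 and -1.42.

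**Figure D1:**
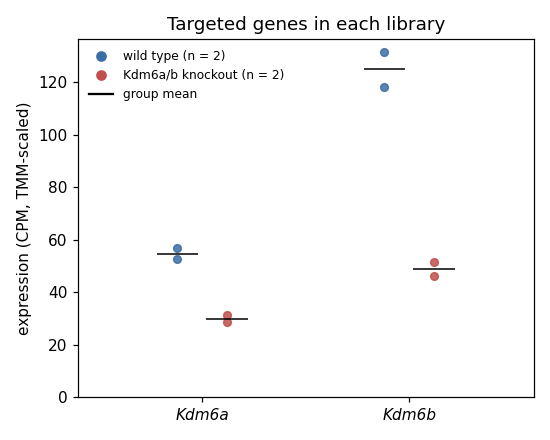
Expression of Kdm6a and Kdm6b in each library, as TMM-scaled CPM on a linear axis from 0, with points for the 2 wild type and 2 knockout libraries and a line at each group mean. Kdm6a means are 54.8 and 30.0 CPM and Kdm6b means are 125 and 48.8 CPM in wild type and knockout.

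Across 13773 tested genes, 1274 differed between knockout and wild type chondrocytes at an edgeR adjusted p below 0.05, of which 498 rose and 776 fell in the knockout. At least 2-fold changes were found for 75 genes that rose and 234 that fell. The largest rise by the naming rule was that of C1qtnf3 (gene 81799), a secreted protein of growth cartilage, by 6.78-fold from 13.2 ± 1.1 to 89.9 ± 5.1 CPM (n = 2 each; log2 fold change 2.76, SE 0.095, edgeR adjusted p = 0.000537). Cytl1, a cytokine-like protein of chondrocytes, rose 6.12-fold from 48.9 ± 8.8 to 300 ± 17 CPM. The proteoglycan gene Ogn rose 3.87-fold, the matrilin gene Matn3 3.86-fold, the cytoskeletal adaptor gene Sorbs2 3.57-fold, the cartilage matrix gene Ucma 3.50-fold and Irs1, an adaptor of the insulin and IGF receptors, 3.22-fold. Slc16a4, of the monocarboxylate transporter family, rose 3.20-fold, the pentraxin gene Ptx3 3.19-fold, the actin gene Acta2 3.03-fold, the tubulin gene Tubb2b 2.99-fold and Rflna 2.92-fold. The SEs of the log2 fold changes of these 12 genes ran from 0.084 for Sorbs2 to 0.18 for Tubb2b, and their largest adjusted p from edgeR was 0.00757, for Tubb2b.

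Apoe (gene 11816), which encodes a lipid carrier protein, was among the largest falls. Its own entry fell 10.0-fold, from 57.5 ± 4.1 to 5.72 ± 1.2 CPM (n = 2 each; log2 fold change -3.33, SE 0.15, edgeR adjusted p = 0.000915). Some Apoe reads stood in 3 further entries named by transcript, and with all entries summed Apoe fell 5.89-fold, from 82.2 ± 1.8 to 13.9 ± 1.8 CPM (log2 fold change -2.56, SE 0.11, edgeR adjusted p = 0.00079), less than Cemip, Ntrk2 and F5. That order is uncertain, since Cemip measured 3.78 and 10.6 CPM in the knockout libraries. In the wild type libraries Ntrk2 measured 27.8 and 58.0 CPM and F5 32.7 and 47.9 CPM. Cemip, which acts in hyaluronan breakdown, fell 7.16-fold, the neurotrophin receptor gene Ntrk2 6.29-fold, the coagulation factor gene F5 6.28-fold, the glutamine transporter gene Slc38a3 5.18-fold and the cytokine gene Il11 5.13-fold. Scara5, a scavenger receptor gene, fell 4.94-fold, the aldehyde dehydrogenase gene Aldh3a1 4.58-fold, the matrilin gene Matn1 4.29-fold, the adhesion receptor gene Adgra1 4.22-fold, the growth factor gene Bmp2 3.92-fold and Hmga1, which encodes a chromatin protein, 3.90-fold. SEs of these log2 fold changes ran from 0.14 for Bmp2 to 0.43 for Cemip, and the largest adjusted p from edgeR was 0.0161, for Scara5. Hmga1, Tubb2b and Acta2 have close relatives in the genome, and their folds are uncertain where the authors' counting split reads between copies.

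**Figure D2:**
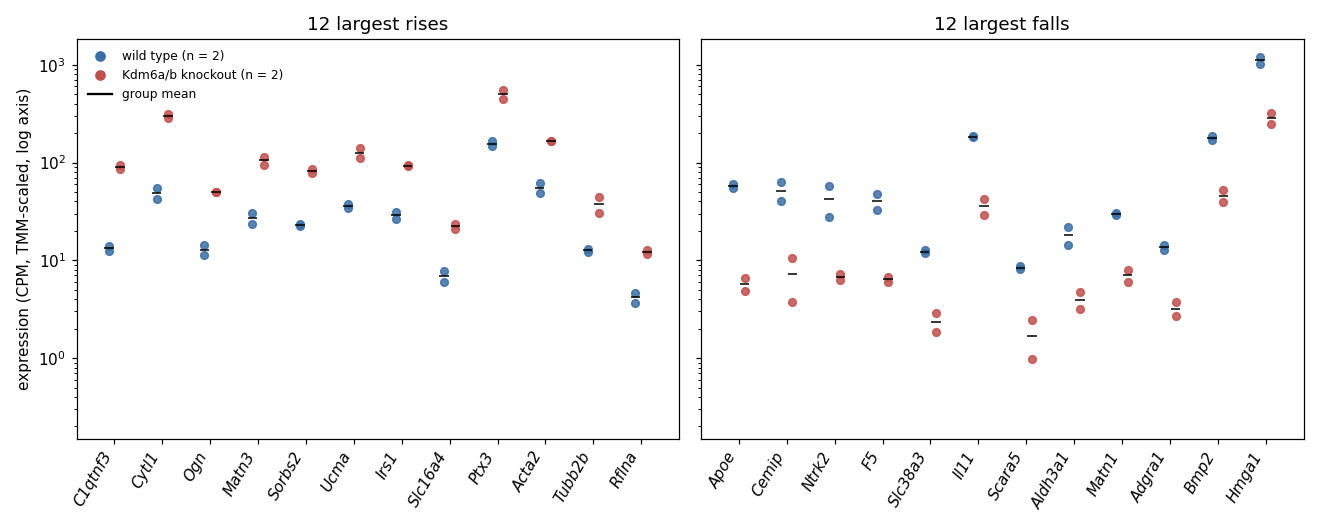
Expression of the 12 genes with the largest rises and the 12 with the largest falls in each library, as TMM-scaled CPM on a log axis, with points for the 2 wild type and 2 knockout libraries and a line at each group mean. C1qtnf3 means are 13.2 and 89.9 CPM and Apoe means, for its own entry, are 57.5 and 5.72 CPM in wild type and knockout.

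The count of changed genes depended on single libraries. Without wild type replicate 1 or wild type replicate 2 no gene passed in edgeR, with 3442 and 2587 genes at an unadjusted p under 0.05, against 540 and 416 genes past an adjusted p of 0.05 in DESeq2. Without knockout replicate 1 or knockout replicate 2, edgeR called 1090 and 1275 genes and DESeq2 659 and 794, where DESeq2 called 1626 with all 4 libraries. The same applies to the counts of members given for each gene list. As a scale for those counts, 498 of all 13773 tested genes rose and 776 fell. An unadjusted p under 0.05 was found for 4016 of them. Adjustment over a short list alone can therefore pass members without a change special to that list. On the deposited FPKM values, tested with limma, 568 genes rose and 512 fell, so the share of falling genes was 47.4% there against 60.9% in edgeR. That fit tested 10952 genes and its values lay higher as a whole. Its median log2 fold change was 0.0492, against 0.00443 in edgeR. Whether this shift accounts for the lower share was not tested.

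Hox genes encode transcription factors that set position along the body axis. Of 25 tested members 9 rose, 0 fell and 16 did not pass, and adjusted over the list alone 16 rose and 0 fell. Hoxa5 rose 1.92-fold from 26.4 ± 2.2 to 50.6 ± 0.57 CPM (n = 2 each; edgeR adjusted p = 0.0038), Hoxa9 rose 3.26-fold from 2.30 ± 0.32 to 7.53 ± 0.12 CPM, Hoxa7 rose 1.97-fold and Hoxa3 rose 2.03-fold. The median log2 fold change of the list was 0.75, and camera with a preset correlation gave an adjusted p of 9.85e-10 (upward). With the correlation estimated from the data the camera adjusted p was 0.415. Markers of macrophages had a median log2 fold change of -0.70 in the same libraries. Whether the authors' counting used strand is not given in the sources used here, so reads from antisense transcripts of the Hox clusters are not told apart.

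Imprinted genes are expressed from the allele of a single parent and are often tied to fetal growth. Of 17 tested members 6 rose, 0 fell and 11 did not pass, and adjusted over the list alone 11 rose and 1, Phlda2, fell. Peg3 rose 2.12-fold from 161 ± 29 to 342 ± 3.3 CPM (n = 2 each; edgeR adjusted p = 0.00757), Mest 2.09-fold, Dlk1 1.63-fold and Plagl1 1.40-fold. Camera gave an adjusted p of 5.42e-05 (upward), and adjusted p = 0.415 with an estimated correlation. Of 21 tested genes of S phase, the period of DNA replication, 5 rose, 0 fell and 16 did not pass, and adjusted over the list alone 9 rose and 0 fell. The replicative helicase genes Mcm6, Mcm5 and Mcm7 rose 2.36-fold, 1.45-fold and 1.28-fold, and the cyclin gene Ccne1 1.54-fold. For S phase camera gave an adjusted p of 0.000247 (upward), and adjusted p = 0.548 with an estimated correlation. Beside the imprinted and S phase lists, macrophage, endothelial and erythroid markers had median log2 fold changes of -0.70, -0.44 and -1.10. These medians are also set beside later lists, but not all lists of other cell types fell. Over markers averaging at least 1 CPM, medians were 0.78 for 2 markers of skeletal muscle, 0.43 for 4 of smooth muscle, 0.30 for 4 of Schwann cells and 0.20 for 3 of adipocytes. The 2 muscle markers, Acta1 and Myod1, did not pass and varied widely in knockout, at 3.08 ± 2.9 and 6.71 ± 5.6 CPM (n = 2). Medians were -0.02 for tendon, -0.12 for osteoclasts, -0.55 for osteoblasts and -0.83 for neutrophils. None of 20 tested genes of G2 and M phase passed in edgeR, before or after adjustment over the list alone, and the camera adjusted p was 0.376. Mki67, a marker of cycling cells, measured 14.2 ± 4.4 CPM in wild type and 9.93 ± 2.4 CPM in knockout (n = 2 each; edgeR adjusted p = 0.222). None of 6 tested CDK inhibitor genes passed over all genes, where adjusted over the list alone Cdkn1a fell (log2 fold change -0.59, SE 0.16), and the camera adjusted p was 0.743.

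Genes of the cartilage matrix moved both ways. Of 21 tested members 6 rose, 4 fell and 11 did not pass, and adjusted over the list alone 10 rose and 4 fell. Col2a1 rose 1.46-fold from 25190 ± 1158 to 36860 ± 359 CPM (n = 2 each; edgeR adjusted p = 0.0156), Col11a1 1.52-fold, Ucma 3.50-fold and Matn3 3.86-fold. Comp, a pentameric matrix glycoprotein gene, fell 3.59-fold from 470 ± 28 to 131 ± 10 CPM (edgeR adjusted p = 0.000915), Matn1 fell 4.29-fold and Chad 2.44-fold. Acan, the main proteoglycan gene, measured 6314 ± 196 and 7935 ± 609 CPM and did not pass (edgeR adjusted p = 0.0687). The list did not pass camera as a whole, with an adjusted p of 0.141, but was among the lists past fry. Among 15 tested chondrocyte transcription factors and cofactors 5 rose, 2 fell and 8 did not pass, and adjusted over the list alone 6 rose and 4 fell, with a camera adjusted p of 0.126. Wwp2 rose 2.22-fold, Sox6 1.69-fold and Zfp521 1.72-fold, and Mef2d fell 1.36-fold. Sox9, the central transcription factor of chondrocytes, measured 639 ± 38 and 562 ± 102 CPM (n = 2 each; edgeR adjusted p = 0.377).

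Among genes of chondrocyte hypertrophy and mineralisation more fell than rose. Of 17 tested members 1 rose, 4 fell and 12 did not pass, with the same counts when adjusted over the list alone. Mgp, a mineralisation inhibitor, fell 2.55-fold from 1343 ± 5.3 to 526 ± 40 CPM (n = 2 each; edgeR adjusted p = 0.00152). Vegfa fell 1.82-fold and Spp1, which encodes osteopontin, 1.57-fold, whereas Mef2c rose 1.99-fold. Col10a1, the collagen gene of hypertrophic chondrocytes, measured 5807 ± 674 and 7762 ± 1404 CPM and did not pass (edgeR adjusted p = 0.118). For this list the camera adjusted p was 0.022 (downward), and adjusted p = 0.467 with an estimated correlation. It was 0.0521 without wild type replicate 2 and 0.0691 without knockout replicate 1. Osteoblast markers, which share Ibsp, Phex and Sp7 with this list, had a median log2 fold change of -1.55 in the same libraries, and of -0.55 over the 3 of them that averaged at least 1 CPM. Macrophage, endothelial and erythroid markers had medians of -0.70, -0.44 and -1.10 there. Of 8 tested genes of resting and articular cartilage 1, Ucma, rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.815). Of 18 genes of fibroblasts and dedifferentiated chondrocytes 0 rose and 3 fell, and adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.464). Cd44 fell 1.67-fold, Col1a2 2.27-fold and Dcn 2.09-fold, and Col5a2 had a log2 fold change of 0.48 (SE 0.13).

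In BMP and TGF-beta signalling 6 of 31 tested genes rose, 8 fell and 17 did not pass, and adjusted over the list alone 8 rose and 11 fell. The ligand genes Bmp2, Inhba and Bmp6 fell 3.92-fold, 2.80-fold and 2.14-fold, and Id3, a BMP target, rose 2.02-fold from 87.1 ± 5.2 to 176 ± 26 CPM (n = 2 each; edgeR adjusted p = 0.0071). The median log2 fold change of this list was 0.08, its mean was -0.10, and its camera test pointed downward without passing (adjusted p = 0.779). In FGF signalling 2 of 14 genes rose, 4 fell and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.108). The receptor genes Fgfr3 and Fgfr2 rose 1.88-fold and 1.92-fold, and the feedback inhibitor genes Spry2 and Spry4 fell 2.18-fold and 1.92-fold. In Wnt signalling 2 of 28 genes rose, 5 fell and 21 did not pass, and adjusted over the list alone 2 rose and 8 fell. Wnt11 fell 2.08-fold and Lef1 1.71-fold, and the receptor genes Fzd8 and Fzd2 rose 1.58-fold and 1.79-fold. Adjusted over the list alone, Sfrp4 and Frzb, genes of Wnt inhibitors, fell too. The direction of the list thus does not give that of the signalling. The camera adjusted p for Wnt signalling was 0.0103 (downward), and adjusted p = 0.596 with an estimated correlation. It was 0.0686 without knockout replicate 1, and macrophage, endothelial and erythroid markers had medians of -0.70, -0.44 and -1.10 in the same libraries. In growth hormone and IGF signalling 1 of 19 genes rose, 4 fell and 14 did not pass, and adjusted over the list alone 2 rose and 5 fell (camera adjusted p = 0.287). Irs1 rose 3.22-fold, while Igfbp4, Pappa and Hmga2 fell 1.70-fold, 1.70-fold and 1.71-fold. None of 10 hedgehog signalling genes passed in edgeR, over all genes or adjusted over the list alone. The camera test of that list pointed upward without passing (adjusted p = 0.815), where its median was -0.0022, 0.0087 with upper-quartile scaling, and its mean -0.07. Gli2 and Ptch1 had log2 fold changes of 0.75 (SE 0.24) and 0.74 (SE 0.25).

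The unfolded protein and amino acid response acts on misfolded proteins and amino acid shortage. Of 17 tested members 0 rose, 10 fell and 7 did not pass, and adjusted over the list alone 13 fell. Herpud1, of the protein degradation machinery of the endoplasmic reticulum, fell 2.26-fold from 185 ± 47 to 81.6 ± 5.7 CPM (n = 2 each; edgeR adjusted p = 0.0129), Dnajb9 2.01-fold, Sdf2l1 1.76-fold and the transcription factor gene Atf4 1.47-fold. By camera its adjusted p was 1.28e-05 (downward), and adjusted p = 0.641 with an estimated correlation. With fry, which tests for movement in 1 direction, its adjusted p was 0.175. The lists that passed fry are named below. Immediate early genes respond within minutes to stimulation or tissue dissociation. Of 23 tested members 0 rose, 9 fell and 14 did not pass, and adjusted over the list alone 14 fell. Jun fell 1.87-fold from 226 ± 12 to 121 ± 2.6 CPM (n = 2 each; edgeR adjusted p = 0.00268) and Btg2 1.75-fold. The heat shock genes Hspa1b and Hspa1a fell with log2 fold changes of -1.14 and -1.12, and their near-identical sequences make the split of reads between them uncertain. The camera adjusted p was 3.15e-06 (downward), and adjusted p = 0.415 with an estimated correlation. The macrophage, endothelial and erythroid marker lists had medians of -0.70, -0.44 and -1.10 in the same libraries. Among 25 inflammatory mediators 1 fell and 24 did not pass, and adjusted over the list alone 3 fell. That gene was Ptgs2, an inducible prostaglandin synthase gene, which fell 2.96-fold from 3266 ± 332 to 1102 ± 168 CPM (n = 2 each; edgeR adjusted p = 0.00263). Adjusted over the list alone Ptges, which also acts in prostaglandin synthesis, and Lif passed too. The median of that list was 0.05, its mean -0.09 and its camera adjusted p 0.376 (downward). The knockout libraries differed in it: its median was 0.48 without knockout replicate 1, where 8 genes rose and 3 fell, and -0.91 without knockout replicate 2, where 13 fell and 0 rose. None of 13 interferon response genes passed in edgeR, over all genes or over the list alone (camera adjusted p = 0.718).

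**Figure D3:**
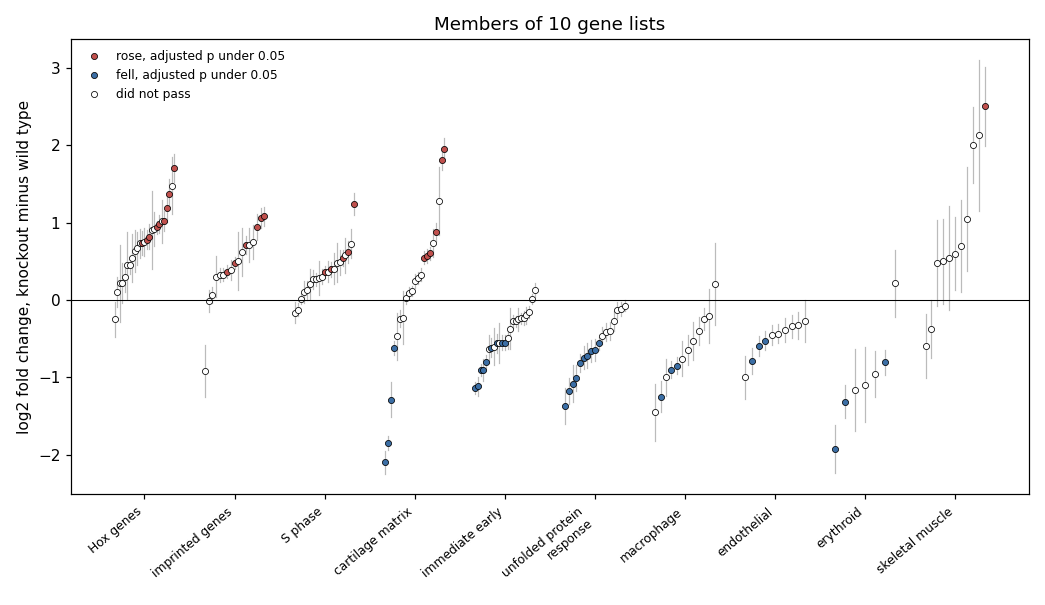
Log2 fold change, knockout minus wild type, of each tested member of 10 gene lists, sorted within each list. Red points rose and blue points fell at an edgeR adjusted p under 0.05, white points did not pass, and bars are 1 SE from 4 libraries. Hox genes lie above 0 with 1 exception, Hoxb9 at -0.25, and the unfolded protein response genes lie below 0.

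Among genes of the chromatin machinery, 0 of 12 tested members of the H3K27 methylation list rose and 1, Phf1, fell 1.44-fold, and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.743). Ezh2, the main methyltransferase gene, had a log2 fold change of 0.44 (SE 0.11, edgeR adjusted p = 0.0514). In the complex that KDM6A joins, 2 of 9 genes fell, Kmt2d 1.32-fold and Kmt2c 1.33-fold, and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.376). Of 16 other histone demethylase genes 2 fell, Kdm7a 1.69-fold and Jmjd1c 1.30-fold, with the same counts adjusted over the list alone. Over these genes camera gave an adjusted p of 0.00812 (downward), and adjusted p = 0.596 with an estimated correlation. It was 0.0618 without wild type replicate 2, 0.0758 without knockout replicate 2 and 0.0929 with the GC and length correction. Beside these genes the medians of the macrophage, endothelial and erythroid markers were -0.70, -0.44 and -1.10. Of 23 developmental transcription factors outside the Hox clusters 1 rose and 2 fell, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.734). Irx3 fell 2.55-fold and Prrx1 1.47-fold, and Alx1 rose 1.46-fold. Of 20 matrix proteases and inhibitors 2 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.743). Timp1 and Mmp16 rose with log2 fold changes of 0.59 and 0.60, and Adamts1 fell 1.74-fold and Mmp10 2.75-fold. Of 20 hypoxia and glycolysis genes 2 rose and 3 fell, and adjusted over the list alone 8 rose and 6 fell (camera adjusted p = 0.42). Ldha, a lactate dehydrogenase gene, rose 1.46-fold, and Vegfa, Adm and Pfkfb3 fell 1.82-fold, 1.63-fold and 1.43-fold.

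Markers of other cell types that a rib digest could hold were counted in the same way. Of 12 macrophage markers 0 rose, 3 fell and 9 did not pass, and adjusted over the list alone 7 fell. Cd14 fell 1.87-fold from 128 ± 4.7 to 68.8 ± 11 CPM (n = 2 each; edgeR adjusted p = 0.00948), Lyz2 1.80-fold and Itgam 2.38-fold. Csf1r, at 6.60 ± 0.16 CPM in wild type and so far below Cd14, had a log2 fold change of -0.76 and did not pass over all genes. Adgre1, Mrc1 and Cd68 did not pass either, with log2 fold changes of 0.21, -0.21 and -0.24, and C1qa, C1qb and C1qc were not tested. Whether the Cd14 reads came from macrophages was not tested. The camera adjusted p was 0.000145 (downward), and adjusted p = 0.415 with an estimated correlation. Of 10 endothelial markers 3 fell, Cdh5 1.51-fold, Tek 1.73-fold and Pecam1 1.44-fold, and adjusted over the list alone 6 fell. For endothelial markers camera gave an adjusted p of 0.00025 (downward), and adjusted p = 0.554 with an estimated correlation. Of 7 erythroid markers 3 fell, and adjusted over the list alone 4 fell. The globin gene Hbb-b1 fell 2.48-fold, and Hba-a1 and Hba-a2 fell 1.75-fold and 3.80-fold, with an uncertain split of reads between those copies. For erythroid markers the camera adjusted p was 0.00938 (downward), and adjusted p = 0.467 with an estimated correlation. Of 7 osteoblast markers 1, Bglap, fell from 1.24 ± 0.10 to 0.352 ± 0.023 CPM, and adjusted over the list alone 4 fell. The camera adjusted p was 0.00783 (downward), adjusted p = 0.467 with an estimated correlation, and 0.0521 without wild type replicate 2. Of 5 mesothelial and epithelial markers 1, Krt19, fell, at 0.566 ± 0.13 and 0.0611 ± 0.043 CPM, and adjusted over the list alone 3 fell. The camera adjusted p was 0.00938 (downward), and adjusted p = 0.467 with an estimated correlation.

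The remaining marker lists did not pass camera. Of 11 skeletal muscle markers 1, Tnnt3, rose, from 0.211 ± 0.12 to 1.21 ± 0.37 CPM, and adjusted over the list alone 2 rose (camera adjusted p = 0.307). Of 7 smooth muscle and pericyte markers 2 rose, Acta2 3.03-fold and Tagln 1.79-fold, over all genes and adjusted over the list alone (camera adjusted p = 0.376). Of 6 Schwann cell markers S100b, which cartilage also expresses, rose 1.61-fold and Mbp fell 2.96-fold, with the same counts adjusted over the list alone (camera adjusted p = 0.759). None of 7 neutrophil, 5 osteoclast, 5 tendon and 3 adipocyte markers passed in edgeR, over all genes or adjusted over each list alone. The camera adjusted p-values were 0.108, 0.743 and 0.734 for the neutrophil, osteoclast and tendon lists, and the adipocyte list had too few tested members. Of those lists, the median log2 fold changes were -0.85, -0.12, -0.02 and 0.20. The Y-linked genes Ddx3y and Uty had at most 5 counts in any library, against 27101 to 30698 counts for the X-linked Ddx3x. None of 3 tested X-linked check genes passed in edgeR, over all genes or adjusted over the list alone (median log2 fold change 0.03, mean -0.04), and Xist was not analysed here.

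Annotation terms carried by the deposited files were tested over 12086 genes with terms, for rising and falling genes apart. Of 2508 terms, 3 were enriched among rising genes by Fisher's exact test. Carbohydrate metabolic process held 13 rising genes of 71 against 2.64 expected (adjusted p = 0.0044), among them the lactate dehydrogenase genes Ldhb and Ldha, which rose 1.75-fold and 1.46-fold. The mitochondrial ATP synthase complex held 6 of 15 against 0.557 expected (adjusted p = 0.012), with Atp5g1 rising 1.35-fold and Atp5o 1.32-fold. Cartilage development held 10 of 51 against 1.90 expected (adjusted p = 0.0123), with Sox6, Col11a1, Nog and Col2a1 among them. Among falling genes 11 terms were enriched. The first was extracellular region, with 46 of 377 genes against 22.1 expected (adjusted p = 0.00399), followed by proteinaceous extracellular matrix, with 26 of 176 against 10.3 (adjusted p = 0.00965), which held Comp and Matn1, and negative regulation of fat cell differentiation, with 10 of 33 against 1.93 (adjusted p = 0.00965). Cellular response to fibroblast growth factor stimulus held 7 of 21 genes against 1.23 expected (adjusted p = 0.0453). The other 7 were cell surface, extracellular matrix, signal transduction, positive regulation of peptidyl-serine phosphorylation, response to peptide hormone, negative regulation of neuron apoptotic process and sensory perception of sound.

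The authors' deposited table compares the same groups with DESeq2 and was read as a check of processing, not as independent evidence. Of 17529 genes that the authors' deposited comparison holds, 1493 had a DESeq2 adjusted p under 0.05, 583 of them higher and 910 lower in the knockout. Of the 1274 genes changed in edgeR, 1205 also passed in the authors' deposited table, all 1205 in the same direction. Log2 fold changes of the authors' deposited table and of edgeR had a Pearson's r of 0.948 across 13773 genes, which are not independent replicates. At a 2-fold change as well, 257 genes passed in both. In the authors' deposited table Kdm6a and Kdm6b had log2 fold changes of -0.85 and -1.33, C1qtnf3 2.72 and the Apoe entry -3.24.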

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

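DESeq2 with each library left out, the summed entries and the GC and length correction were chosen after seeing the data. In every called gene both knockout libraries lay on the same side of both wild type libraries. Direction could therefore hardly change, and all 103 named genes past the threshold kept it under every alternative that gave them a value. Of these, 102 still passed with DESeq2 size factors, upper-quartile scaling and limma-voom, 99 with the DESeq2 Wald test, 93 with the GC and length correction and 90 on log2(FPKM + 1). Against 1274 changed genes, the count was 720 with no filter on low counts, where 17547 genes were tested, 2454 at an adjusted p of 0.1 and 309 with a 2-fold change as well. It was 0 in limma on log2(FPKM + 1) with no filter, with 4107 genes at an unadjusted p under 0.05, and there Kdm6a had a log2 fold change of -0.73 and Kdm6b of -1.21 without passing. The cause was not tested. The count ran from 0 to 1275 with 1 library left out. Without wild type replicate 1 or 2, edgeR called 0 genes, and DESeq2 called 540 and 416. Without knockout replicate 1 or 2, edgeR called 1090 and 1275, and DESeq2 659 and 794. Kdm6a ran from -0.93 to -0.80 and Kdm6b from -1.43 to -1.27, passing when a knockout library was left out and not when a wild type library was.

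The differences between replicates 1 and 2 in the groups had a correlation of 0.107 across genes. On the second principal component, with 23.1% of variance, both replicates 1 lay above 0 (12.9 and 20.2) and both replicates 2 below (-11.1 and -22.0). The third, with 18%, set them in opposite ways. Pairing is neither shown nor excluded by these values. The labels give no shared animal or day, so the numbers are not taken as pairs. With a replicate block the count was 2316 genes and 108 annotation terms. Against 13 lists past camera, 0 lists passed with an estimated correlation, 10 to 17 with a library left out, and 7 with fry, which were 6 of the 13 and the cartilage matrix list. By fry the adjusted p was 0.0237 for the Hox, imprinted, immediate early, macrophage and erythroid lists, and 0.0269 for hypertrophy and mineralisation. Annotation terms numbered 41 with genes changed in DESeq2, against 14. Genes shared with the authors' deposited table were 257 with a 2-fold change as well, against 1205. A fit with sex as a term was not run, since Y-linked genes were near 0 in every library. Of 7 adipocyte markers 3 had enough reads to be tested, and whether depth or a lack of expression left out the rest was not tested. In simulated data with 2 libraries per group 49.3% of 1.5-fold changes were recovered, a share not split by depth.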

Other observations

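The tests of the chest level, of the shares of other cells and of macrophages were chosen only after the results they bear on were seen, and the GC and length correction and the summed entries were added after seeing the data. The Hox clusters differed in how many members passed in edgeR. In the Hoxa cluster 6 of 9 tested genes rose, with a median log2 fold change of 1.02 (SE 0.15, bootstrap over genes), and all 9 values were positive. In the Hoxb cluster 0 of 8 passed, with a median of 0.26 (SE 0.12) and a range from -0.25 to 0.73. The Hoxc and Hoxd clusters had 2 of 5 and 1 of 3 genes that rose, with medians of 0.74 and 0.91. The difference between clusters was not tested.

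Of 12 tested genes with the term for phosphatases that switch off MAP kinases, a term picked after its result was seen, 5 fell against 0.702 expected. The term did not pass by Fisher's exact test (adjusted p = 0.0585). Dusp5 fell 3.37-fold from 37.7 ± 2.7 to 11.2 ± 0.97 CPM (n = 2 each; edgeR adjusted p = 0.00152), Dusp6 2.12-fold, Dusp4 2.10-fold, Dusp10 1.79-fold and Dusp14 1.64-fold. Of 39 genes of respiratory complex I, picked in the same way, 7 rose against 1.45 expected, among them Ndufb4 by 1.46-fold, and the term did not pass (adjusted p = 0.183).

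Of 25 tested Hox genes 24 had log2 fold changes above 0 and 9 passed in edgeR, with a median of 0.75 (SE 0.089). After the correction for transcript GC content and length the median was 0.699 (SE 0.077), so that bias does not account for it. Hox genes of paralogue groups 1 to 5, whose domains begin in front of the chest, had a median of 0.744 (SE 0.12), which argues against ribs from a lower level as the whole source. These SEs are bootstraps over genes, which share clusters and libraries, so they leave out the spread between libraries. The Hox median lay above the cartilage matrix median by 0.502 (SE 0.212, also a bootstrap over genes). A higher share of chondrocytes would raise all their transcripts alike and leave no such gap. The gap thus argues against that share as the whole source of the Hox rise. Matrix genes went both ways with an SD of 1.03, so a partial contribution of a higher share stays open. An effect of the missing demethylases may be involved and was not tested apart from such a share.

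The Apoe entry on its own had a log2 fold change of -3.33. With its entries summed it was -2.56, so split entries made the fall look larger and did not create it. The summed fall was smaller than those of Cemip, Ntrk2 and F5, an order left uncertain by the spread of these 3 genes between replicates. Macrophages express Apoe strongly, but the median of 12 macrophage markers was -0.703 (SE 0.17) and the lowest of them was -1.45, so a loss of macrophages of that size could not account for the whole fall. An effect of the knockout on Apoe in chondrocytes may remain, as an untested hypothesis.

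Macrophage, endothelial and erythroid markers had median log2 fold changes of -0.70, -0.44 and -1.10. A higher share of chondrocytes would lower markers of all other cell types alike. Only markers averaging at least 1 CPM were used. Of 4 lists with at least 5 of them, 3 had a median below 0 by more than 2 SE, neutrophils at -0.83 among them. The highest median was -0.116 for osteoclasts (SE 0.23, bootstrap over markers, which leaves out the spread between libraries). Of lists with 2 to 4, erythroid and osteoblast markers had medians of -1.14 and -0.55. The others were 0.43 for smooth muscle, 0.30 for Schwann cells, -0.02 for tendon, 0.20 for adipocytes and 0.78 for skeletal muscle. The medians near or above 0 go against a like fall of all other cells, but rest on few markers. Acta2 and S100b can be made by cultured chondrocytes, so a higher share of chondrocytes stays open. Fewer blood and vessel cells through dissection or genotype may account for the falls as well.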
